A study of Mus musculus with 32 samples.

How the data were processed

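The series holds 32 samples in 16 groups of 2 libraries each, all from mouse cell lines. Scid.adh.2c2 is a pro-T-like line derived from a lymphoma, and ILC2/b6 is a line of group 2 innate lymphoid cells grown, per the labels' protocols, with IL-2, IL-7 and IL-33 at 10 ng/ml. Of the samples, 8 are RNA-seq libraries (cells given a control guide or a guide against Bcl11b, in each line), 16 are ChIP-seq libraries (Bcl11b, GATA3, Runx1 and Runx3, in each line) and 8 are input libraries. For ChIP-seq the cells were fixed with DSG and then formaldehyde, per the labels' protocols. The inputs come in 2 kinds of fixation, and which input served which ChIP is not given in the sources used here. Reads were single-end and 50 nt long. The RNA library kit named in the labels is not one that marks strand by its name, so a gene and an overlapping antisense gene cannot be told apart. The labels do not say whether the replicates are separate cultures, so p-values measure the spread between these libraries, whatever its source.

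The authors deposited RPKM values (reads per kilobase of transcript, scaled to sequencing depth) for 24475 genes in each of 2 tables, 1 per cell line, with 1 column per library. The cell line of a table is known from the table's name. Per the submitters' processing notes, the tools used were Bowtie 1.1.1, HOMER, RSEM 1.2.25, STAR 2.4.0, Trimmomatic and edgeR 3.6.8, with the builds mm9 and NCBIM37; their roles are not given. The authors also deposited 8 peak lists with a peak score for each interval, 1 list per factor and line. Per the file headers, each list was made from the 2 replicate libraries together as a set filtered by the irreproducible discovery rate and annotated with HOMER on mm9, so peaks cannot be compared between replicates. The lowest score in a list was 15.0 or 15.1, and all intervals of a list had the same width, between 237 and 317 bp. The scores are the authors' and are used only to rank or describe peaks within a list. Read-level data and the input libraries were not used here.

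Depth was recovered from the steps of the RPKM values. Values low and precise enough to test, 3600 to 4190 per library, all came out as whole reads within a tolerance of 0.1 read. This gave totals of 34.7 to 43.7 M reads (M, mega). At these depths 1 read on a transcript of 2 kb was worth 0.0114 to 0.0144 RPKM, and 3 reads were worth 0.0343 to 0.0432 RPKM. These levels cover counting error only.

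Because the 2 tables hold each line apart, changes were tested within a table. Genes with at least 1 RPKM in at least 2 of the libraries of a line were tested on log2(RPKM + 0.5) with limma 3.58.1 (R 4.3.3), with a mean-variance trend and Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05. Fold changes are on that scale, which understates the change of low genes. An adjusted p given for a gene is from this limma fit unless another setting is named beside it. The difference between lines was the limma interaction contrast over all 8 RNA libraries, ILC2/b6 minus Scid.adh.2c2, in which a factor per gene and table cancels. Of the genes in that contrast, 545 have different transcript models in the 2 tables. On libraries simulated at the recovered depths with the spread seen in each line and known changes in 200 genes, the test recovered 67.2% of 1.5-fold, 89.6% of 2-fold and 98.5% of 4-fold changes for Scid.adh.2c2, with 7 false calls among 177. For ILC2/b6 it recovered 71.6%, 92.4% and 98.5%, with 4 false calls among 178. The simulated libraries had fewer changed genes than were called in the data. They held no scaling shift and no noise shared by the libraries of a group. Their false calls therefore do not measure those among the real calls.

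There were 20 gene lists, of partner factors, T-lineage identity, Notch response, stem and progenitor cells, NK and innate effector genes, ILC2 identity and effector genes, ILC3 and type 17 genes, regulatory and checkpoint receptors, trafficking and adhesion, B lineage, myeloid and mast cells, erythroid cells, stroma, cell cycle, p53 response, interferon response, immediate early and heat shock genes, cholesterol synthesis, glycolysis and hypoxia, and cytokine signal regulators. Some genes stand on several lists, such as Il2ra and Ptcra. Lists with at least 5 tested members were tested with camera in limma, with a preset correlation of 0.01 and, beside it, with an estimated correlation. Adjustment was over the 15 lists tested in each line. No list call held with an estimated correlation in either line. That version has little power with 2 libraries per group. In Scid.adh.2c2 the NK and innate effector list lost its call with an estimated correlation of -0.034, below the preset. A lost call therefore does not by itself show that correlated members explain a list. The estimated correlation was, however, 0.703 for glycolysis and hypoxia and 0.555 for cholesterol synthesis in that line, far above the preset. For these lists the preset overstates the evidence if the estimates hold, and correlated members remain a possible reason for the calls.

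Intervals of 2 lists were called overlapping when they shared at least 1 bp. A chance level was obtained by moving the peaks of 1 list by 1000000 or 2000000 bp in both directions. Bcl11b peaks were assigned to the gene the authors' annotation names, at any distance, and promoter peaks are those annotated as promoter-TSS. Shares of peaks or genes were compared with two-sided Fisher's exact tests, with a Cochran-Mantel-Haenszel test over 10 strata of mean expression for genes; peaks and genes are not independent replicates. Benjamini-Hochberg adjustment was over 12 comparisons of co-occupancy, 84 of peaks at genes and 8 overlaps of calls between lines. Gene names blank or unknown in the peak annotation were looked up by transcript, in the RPKM tables and then in a RefSeq table of the assembly GRCm38.p6, used for names only. Coordinates are those of the files, in mm9. No genome sequence was used, so no motif was searched.

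The sample groups, tests, gene lists, alternatives and the rule for the genes and peaks named were fixed before the data were examined. The rule takes, per line, Bcl11b and the partner factors; the 10 genes with the largest rise and the 10 with the largest fall among called genes whose libraries do not overlap between groups; and up to 4 members of each list, called members first and then by size. Predicted or clone names are left out, which removed 2 of the top rises and 1 of the top falls in Scid.adh.2c2. For the difference between lines it takes the 5 largest in each direction with a gene symbol and list members past the threshold. For peaks it takes the 3 with the highest score among shared and among line-restricted Bcl11b peaks, and the highest-scoring peak at each named changed gene. Not every gene that the rule takes is reported here. The rule does not say which line's score ranks the shared peaks, so the first 3 of each line's list are given. The alternatives were other pseudocounts, filters and scalings, no trend, a joint fit, a replicate block, leaving out each library in turn, a 2-fold minimum, other overlap rules and stricter peak lists. Tests on reads recovered from RPKM with voom weights, and splits into promoter peaks and peaks outside promoters, were chosen after seeing the data, as were the difference between lines among genes tested in both and the splits of peaks at genes into shared and line-restricted peaks and by direction of change. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.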

Results

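RNA-seq measured mRNA in 2 mouse cell lines given a control guide or a guide against Bcl11b, a zinc finger transcription factor needed for T-lineage commitment and for ILC2 function. Scid.adh.2c2 is a pro-T-like line and ILC2/b6 is a line of group 2 innate lymphoid cells, which make type 2 cytokines. Each of the 4 RNA groups had 2 libraries. ChIP-seq measured where Bcl11b and 3 partner factors (GATA3, Runx1 and Runx3) bound in each line, as 1 peak list from 2 libraries per factor and line. In Scid.adh.2c2 the control libraries held 43.7 and 34.7 M reads and the Bcl11b guide libraries 40.8 and 40.2 M reads. In ILC2/b6 the control libraries held 37.4 and 35.2 M reads and the Bcl11b guide libraries 38.7 and 35.0 M reads. The share of reads on the listed genes was 73.9% and 74.7% in the Scid.adh.2c2 control libraries and 76.9% and 76.8% with the Bcl11b guide, and lay between 77.9% and 78.1% in ILC2/b6. Means are given ± SD with n = 2 libraries, and log2 fold changes ± SE.

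Bcl11b, the targeted gene (chr12:109148613-109241624), had 47.0 and 49.5 RPKM in the Scid.adh.2c2 control libraries and 47.1 and 46.8 RPKM with the Bcl11b guide. In ILC2/b6 it had 6.85 and 6.33 RPKM in the control libraries and 7.04 and 7.24 RPKM with the guide. The log2 fold change was -0.04 ± 0.04 in Scid.adh.2c2 (adjusted p = 0.455) and 0.11 ± 0.06 in ILC2/b6 (adjusted p = 0.278), so neither passed the test. In Scid.adh.2c2 it passed with median-centred values (-0.17, adjusted p = 0.00856) and with quantile normalization (-0.11, adjusted p = 0.046). A frameshift at a guide site need not lower the mRNA, so these levels do not check the labels.

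The comparison of guides in Scid.adh.2c2 asks which genes depend on Bcl11b in a pro-T-like cell. With the Bcl11b guide, Il2rb, the beta chain of the IL-2 and IL-15 receptors (chr15:78310979-78325496), rose from 1.68 ± 0.210 to 126 ± 0.428 RPKM (log2 fold change 5.86 ± 0.07, adjusted p = 1.76e-08). Ncr1, the activating receptor NKp46 (chr7:4289326-4296766), rose from 0.2 ± 0.082 to 37.0 ± 0.95 RPKM (5.75 ± 0.10, adjusted p = 3.83e-08). Rag1, the recombinase of antigen receptor genes (chr2:101478411-101489689), fell from 69.9 ± 8.22 to 11.4 ± 0.487 RPKM (-2.57 ± 0.08, adjusted p = 3.48e-07). Among the partner factors, Runx3 (chr4:134676560-134733905) rose from 3.18 ± 0.145 to 18.1 ± 0.191 RPKM (2.34 ± 0.07, adjusted p = 2.58e-07), while Tcf7, a T-cell transcription factor (chr11:52065785-52096516), fell from 389 ± 0.526 to 217 ± 1.49 RPKM (-0.84 ± 0.04, adjusted p = 2.74e-06).

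Of the other genes with the largest rises, Ccl3, a chemokine, reached 39.9 RPKM from 0.260 RPKM (log2 fold change 5.73). The Ly6 genes Ly6c2, Ly6g, Ly6c1 and Ly6a rose by 5.68, 5.55, 5.50 and 5.21 log2 units, and the interferon-inducible GTPase gene Gvin1 by 5.66. These genes have close paralogs, so how reads divide among family members is uncertain. Of the other largest falls, Fbp1, an enzyme of gluconeogenesis, went from 35.3 to 4.85 RPKM (-2.74) and Arsi from 44.7 to 7.31 RPKM (-2.53). Stc1, Rhox7a and Mtus2 fell with log2 fold changes of -2.69, -2.31 and -2.29. The hypoxia-responsive genes Ndrg1, Ankrd37 and Mgarp fell with -3.13 ± 0.36, -2.43 ± 0.31 and -2.24 ± 0.33, and their control libraries were far apart. Ndrg1 in Scid.adh.2c2 had 117 and 45.9 RPKM in the control libraries, and its fold was -2.46 without control replicate 1 and -3.80 without control replicate 2.

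**Figure D1:**
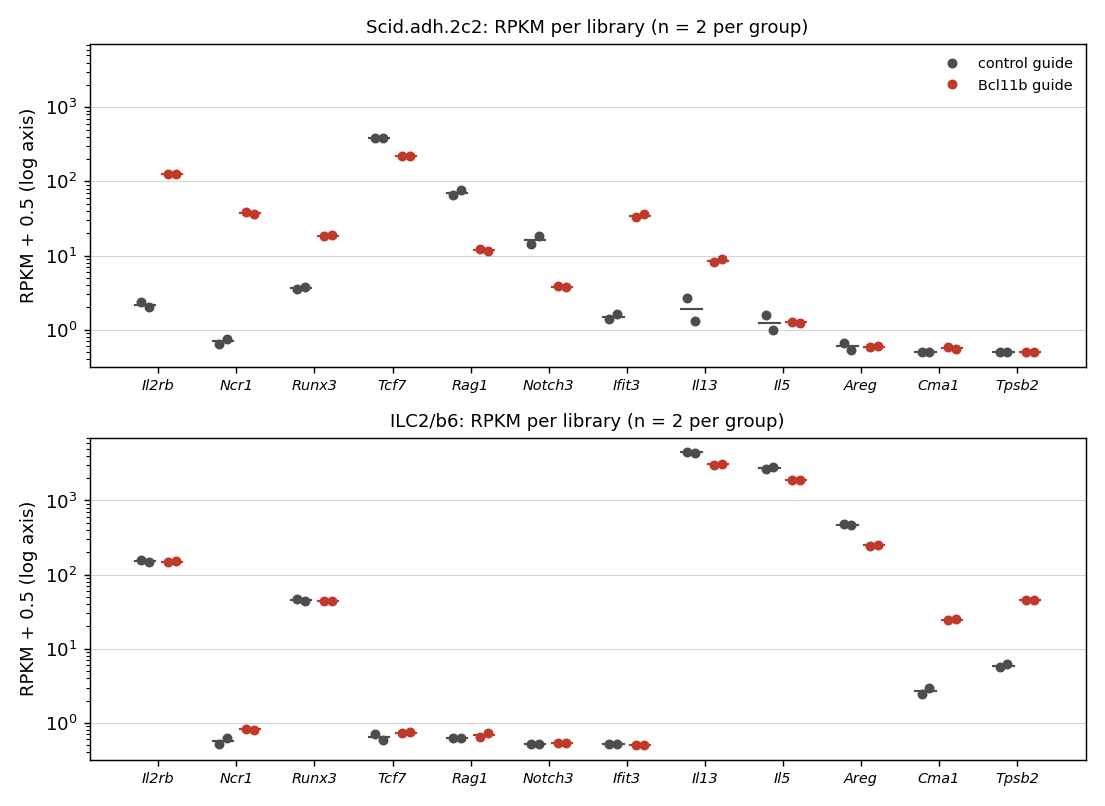
RPKM + 0.5 per library on a log axis for 12 named genes in Scid.adh.2c2 and ILC2/b6, with control guide and Bcl11b guide libraries as points and the geometric mean of each group of 2 as a horizontal bar. Il2rb and Ncr1 stand higher with the Bcl11b guide in Scid.adh.2c2, and Cma1 and Tpsb2 in ILC2/b6.

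Some lists rose in Scid.adh.2c2 by camera with the preset correlation. Counts are of tested members. There, 18 of 39 NK and innate effector genes, 8 of 21 ILC3 and type 17 genes and 9 of 12 Notch response genes were tested. A gene under 1 RPKM in both control libraries was tested only if it reached 1 RPKM in both Bcl11b guide libraries. The filter therefore favours rises in lists of genes that the control cells hardly express. All 22 interferon response genes tested rose, 22 also when adjusted over the list alone, with a median log2 fold change of 2.49 (camera adjusted p = 7.52e-14; adjusted p = 0.135 with an estimated correlation). Ifit3 rose from 0.998 ± 0.162 to 34.0 ± 2.03 RPKM, Oasl2 by 4.23, Ifi44 by 4.11 and Rsad2 by 3.95 log2 units. Of 18 NK and innate effector genes, 14 rose, 1 fell and 3 were not called, 16 being called when adjusted over the list alone (median 2.58, camera adjusted p = 3.66e-06; adjusted p = 0.135 with an estimated correlation). Nkg7, a granule protein, rose by 4.65 and Tyrobp, an adaptor of activating receptors, by 4.15 log2 units. Of 15 trafficking and adhesion genes, 13 rose, 1 fell and 1 was not called, 15 being called when adjusted over the list alone (median 1.94, camera adjusted p = 4.15e-06; adjusted p = 0.135 with an estimated correlation). The chemokine receptor genes Cxcr6 and Cxcr3 rose by 3.47 and 3.12 log2 units. Of 8 ILC3 and type 17 genes, 5 rose and 3 were not called, 6 being called when adjusted over the list alone (median 1.38, camera adjusted p = 0.0493; adjusted p = 0.328 with an estimated correlation). Ltb rose by 2.94 and Batf by 2.38 log2 units. Of 13 p53 response genes, 9 rose, 1 fell and 3 were not called, 10 being called when adjusted over the list alone (median 0.34, camera adjusted p = 0.0104; adjusted p = 0.247 with an estimated correlation). Bbc3, a promoter of apoptosis, rose from 2.30 to 12.5 RPKM. Without the expression filter the ILC3 and type 17 list had an adjusted p of 0.223.

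Other lists fell there by the same test. All 9 Notch response genes tested fell, 9 also when adjusted over the list alone. Their median was -1.77 (camera adjusted p = 1.28e-08, and 0.135 with an estimated correlation). Notch3 fell from 15.8 ± 2.75 to 3.30 ± 0.0347 RPKM, Il2ra, the alpha chain of the IL-2 receptor, from 159 ± 12.8 to 43.5 ± 1.1 RPKM, and Hes5 from 14.9 to 3.71 RPKM. Of 17 cholesterol synthesis genes, 14 fell and 3 were not called, 15 being called when adjusted over the list alone (median -0.35, camera adjusted p = 3.53e-06; adjusted p = 0.397 with an estimated correlation). Lss, Fdps and Dhcr7, enzymes of the pathway, fell with -0.60, -0.59 and -0.55. Of 21 glycolysis and hypoxia genes, 1 rose, 16 fell and 4 were not called, 18 being called when adjusted over the list alone (median -0.78, camera adjusted p = 3.66e-06; adjusted p = 0.456 with an estimated correlation). Bnip3 fell from 33.4 ± 11.8 to 9.75 ± 2.61 RPKM and Egln3 from 59.4 ± 15.2 to 19.0 ± 3.10 RPKM. Of 23 cell cycle genes, 3 rose, 9 fell and 11 were not called, 12 being called when adjusted over the list alone (median -0.07, camera adjusted p = 0.0147; adjusted p = 0.247 with an estimated correlation). Mcm7, Tyms, Mcm6 and Pcna, of DNA replication, fell with -0.41, -0.37, -0.35 and -0.29. With quantile normalization the cell cycle list had an adjusted p of 0.0769.

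The remaining lists were not called in Scid.adh.2c2. Of 23 T-lineage identity genes, 10 rose, 9 fell and 4 were not called, 20 being called when adjusted over the list alone (median -0.14, camera adjusted p = 0.326; adjusted p = 0.464 with an estimated correlation). Lef1 fell from 38.0 ± 4.40 to 8.24 ± 0.0516 RPKM and Ptcra, the pre-T-cell receptor alpha chain, from 31.4 to 7.92 RPKM. Of 18 ILC2 identity and effector genes, 10 rose, 6 fell and 2 were not called, 16 being called when adjusted over the list alone (median 0.57, camera adjusted p = 0.469; adjusted p = 0.641 with an estimated correlation). Arg1, Csf2, Il4 and Lif rose by 3.99, 3.65, 2.59 and 2.28 log2 units. Of 10 partner factors, 4 rose, 3 fell and 3 were not called, 8 being called when adjusted over the list alone, and the median of 0.04 and mean of 0.20 were positive while the test pointed down (camera adjusted p = 0.984; adjusted p = 0.991 with an estimated correlation). Ikzf1 and Ets1 rose by 0.62 and 0.33, and Tcf12 and Tcf3 fell with -0.50 and -0.24. Gata3 rose by 0.22 ± 0.05 (adjusted p = 0.00506), with an adjusted p of 0.142 with median-centred values and 0.0671 without Bcl11b guide replicate 2. Runx1, Cbfb and Gfi1 did not pass the test, at -0.05, 0.11 and -0.03. Runx1 passed with median-centred values (adjusted p = 0.0132) and without control replicate 1 (0.0410), Cbfb without control replicate 2 (0.00389) and Gfi1 with median-centred values (0.0362).

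Of 5 regulatory and checkpoint receptor genes tested in Scid.adh.2c2, 3 rose, 1 fell and 1 was not called, 4 being called when adjusted over the list alone (median 0.81, camera adjusted p = 0.369; adjusted p = 0.481 with an estimated correlation). Cd200r1, Btla and Tnfrsf9 rose by 2.25, 1.64 and 0.81, and Il10 fell with -1.58. Of 7 immediate early and heat shock genes, 3 rose, 2 fell and 2 were not called, 6 being called when adjusted over the list alone (median 0.19, camera adjusted p = 0.333; adjusted p = 0.464 with an estimated correlation). Egr1, Junb and Jund rose by 2.42, 1.64 and 0.99, and Dusp2 fell with -0.46. Of 18 cytokine signal regulators, 12 rose, 5 fell and 1 was not called, 17 being called when adjusted over the list alone (median 0.43, camera adjusted p = 0.186; adjusted p = 0.397 with an estimated correlation). Socs3, an inhibitor of cytokine signals, fell from 13.0 to 3.68 RPKM, while Prdm1 and Socs2 rose by 1.71 and 1.69. Markers of other cell types were mostly too few to test as lists. Of these, Spi1, the myeloid factor PU.1, rose from 0.01 to 3.01 RPKM and Flt3 fell with -1.05. Cd22, a B-cell gene, rose by 1.42, the mast cell protease gene Cpa3 rose from 22.4 to 62.5 RPKM, and Cebpb and Itgam rose by 0.92 and 0.76, while Cd68 stood at 0.25 (adjusted p = 0.0779, and 0.0319 without control replicate 1). The globin genes Hba-a1 and Hba-a2, which overlap, rose by 2.35 and 2.28, and Pdgfrb, a stromal gene, fell with -1.75.

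In all, 5908 of 10221 tested genes (57.8%) were called in Scid.adh.2c2, of which 3589 rose and 2319 fell. At 2-fold or more there were 862, of which 690 rose and 172 fell. The libraries of the groups did not overlap for 8180 genes (80%), against 33.3% by chance. The split by direction depends on the scaling: median-centring moved the median of all genes by -0.13 log2 units and gave 2466 that rose and 3934 that fell (38.5% rose, against 60.7%), and quantile normalization gave 2443 and 3918 (38.4% rose). At 2-fold or more, 80% rose as deposited, 73.1% with median-centred values and 66.0% with quantile normalization. Without Bcl11b guide replicate 1 the count was 3818, and without replicate 2 it was 3760.

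The same comparison in ILC2/b6 asks which genes depend on Bcl11b in an innate lymphoid cell. With the Bcl11b guide, Cma1, a chymase (chr14:56560288-56563512), rose from 2.21 ± 0.402 to 24.2 ± 0.207 RPKM (log2 fold change 3.20, adjusted p = 9.33e-06), and Tpsb2, a tryptase (chr17:25503278-25505037), from 5.42 ± 0.344 to 44.8 ± 0.145 RPKM (2.94 ± 0.05, adjusted p = 8.49e-07). Areg, a growth factor of the EGF family (chr5:91568625-91577458), fell from 473 ± 4.52 to 248.6 ± 7.94 RPKM (-0.93 ± 0.04, adjusted p = 2.08e-05). Il5 (chr11:53534296-53538605) fell from 2770 ± 140 to 1877 ± 4.56 RPKM (-0.56 ± 0.05, adjusted p = 0.000518) and Il13 (chr11:53444825-53448204) from 4439 ± 46.9 to 3088 ± 88.9 RPKM (-0.52 ± 0.04, adjusted p = 0.000487). In a joint fit of the 8 libraries, which shares 1 estimate of the spread, Il5 and Il13 no longer passed (adjusted p = 0.0591 and 0.223). That estimate takes in Scid.adh.2c2, where both genes were low. Its control libraries had 1.062 and 0.49 RPKM of Il5 and 2.21 and 0.816 RPKM of Il13. Tpsb2 has a close paralog, so its reads are not certainly its own.

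Of the other genes with the largest rises in ILC2/b6, Tmem119, C5ar1, a complement receptor, and Cd244, a receptor of natural killer cells, rose from under 0.500 RPKM by 2.93, 2.90 and 2.80 log2 units. Pilrb1, Pga5, Ccbe1, P2rx1 and Pilra rose by 1.92, 1.87, 1.73, 1.71 and 1.64. The largest falls were of Snord58b (-2.78), Mir6970 (-1.37) and, further down, Scarna17 (-1.13) and Mir5130 (-1.07), short RNAs that these libraries measure poorly. Of protein-coding genes, Cxcl3, a chemokine, fell from 27.8 ± 7.09 to 10.8 ± 0.424 RPKM (-1.31). Adgrg5, Tmem86a, Prr5l and Smpdl3a fell with -1.20, -1.18, -1.17 and -1.16, and Iapp with -1.04. The adjusted p was 0.136 for Iapp in ILC2/b6 without control replicate 1, its fold was -0.67 without Bcl11b guide replicate 1, and the adjusted p was 0.0524 for Mir6970 without control replicate 2.

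Of 12 T-lineage identity genes tested in ILC2/b6, 7 fell and 5 were not called, 8 being called when adjusted over the list alone (median -0.21, camera adjusted p = 0.00117; adjusted p = 0.464 with an estimated correlation). Ubash3a, Grap2 and Lat, of antigen receptor signalling, fell with -0.75, -0.52 and -0.41. Of 23 glycolysis and hypoxia genes, 2 rose, 6 fell and 15 were not called, 10 being called when adjusted over the list alone (median -0.08, camera adjusted p = 0.00117; adjusted p = 0.464 with an estimated correlation). Slc2a3, Egln3 and Pkm fell with -0.53, -0.32 and -0.27, and P4ha1 rose by 0.28. Of 12 immediate early and heat shock genes, 1 rose, 5 fell and 6 were not called, 7 being called when adjusted over the list alone (median -0.12, camera adjusted p = 0.00187; adjusted p = 0.464 with an estimated correlation). Egr1 fell from 29.0 ± 2.00 to 16.7 ± 0.178 RPKM, and Fos, Dusp1 and Dusp2 fell with -0.82, -0.77 and -0.57. Dusp2 had an adjusted p of 0.109 without control replicate 1 and 0.0661 without Bcl11b guide replicate 2. Without the expression filter the T-lineage list had an adjusted p of 0.127 and Fos one of 0.124, and in the joint fit Egln3, P4ha1 and Pkm had 0.219, 0.165 and 0.139.

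Of 10 interferon response genes tested in ILC2/b6, 3 rose and 7 were not called, 6 being called when adjusted over the list alone (median 0.14, camera adjusted p = 0.0375; adjusted p = 0.504 with an estimated correlation). The call ended without control replicate 2 (0.0571), without Bcl11b guide replicate 2 (0.104) and without the expression filter (0.0590). Ifi27, Ddx58 and Bst2 rose by 0.34, 0.28 and 0.14, and each of the 3 calls ended without at least 1 library. The adjusted p without Bcl11b guide replicate 2 was 0.0615, 0.185 and 0.305, that of Ddx58 was 0.133 without control replicate 1, and that of Bst2 was 0.0658 without control replicate 2 and 0.173 without Bcl11b guide replicate 1. Of 10 partner factors, 2 fell and 8 were not called, 4 being called when adjusted over the list alone (median -0.07, camera adjusted p = 0.0384; adjusted p = 0.464 with an estimated correlation). The call ended without control replicate 2 (0.0771), without Bcl11b guide replicate 1 (0.0728), without the expression filter (0.0687) and with quantile normalization (0.0775). Runx2 fell from 5.85 ± 0.151 to 4.54 ± 0.0608 RPKM, and Ets1 fell with -0.18 but had an adjusted p of 0.126 without Bcl11b guide replicate 1 and 0.112 without replicate 2. Gata3, Runx1, Runx3, Cbfb, Ikzf1, Tcf3, Gfi1 and Tcf12 did not pass, at 0.08, -0.01, -0.03, -0.03, 0.02, -0.10, -0.23 and -0.22, though Gfi1 passed without Bcl11b guide replicate 2 (0.0192) and Tcf12 with median-centred values (0.0349). Of 23 cell cycle genes, 2 fell and 21 were not called, 1 being called when adjusted over the list alone (median -0.03, camera adjusted p = 0.0465; adjusted p = 0.564 with an estimated correlation). The call ended without control replicate 2 (0.142), without Bcl11b guide replicate 2 (0.24) and with quantile normalization (0.435). Rrm2 fell with -0.26 and Mcm2 with -0.16, the latter with an adjusted p of 0.0864 without control replicate 1, 0.0986 without Bcl11b guide replicate 1 and 0.262 without replicate 2.

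The other lists were not called in ILC2/b6. Of 30 ILC2 identity and effector genes, 5 rose, 6 fell and 19 were not called, 14 being called when adjusted over the list alone (median -0.02, camera adjusted p = 0.423; adjusted p = 0.726 with an estimated correlation). Deptor, an mTOR inhibitor, rose by 0.61. Of 13 NK and innate effector genes, 5 rose, 2 fell and 6 were not called, 8 being called when adjusted over the list alone (median 0.10, camera adjusted p = 0.127; adjusted p = 0.504 with an estimated correlation). This list passed without Bcl11b guide replicate 1 (0.0416) and without replicate 2 (0.0279). Fcer1g, an Fc receptor chain, rose from 0.630 ± 0.272 to 2.91 ± 0.533 RPKM, and Il18rap and Gzmc rose by 0.48 and 0.41. Of 11 regulatory and checkpoint receptor genes, 3 rose, 1 fell and 7 were not called, 7 being called when adjusted over the list alone (median 0.18, camera adjusted p = 0.0936; adjusted p = 0.564 with an estimated correlation). Tnfrsf9, a costimulatory receptor, rose from 424 ± 31.4 to 713 ± 1.56 RPKM, Icos by 0.45 and Nt5e by 0.43, and Ctla4 fell with -0.33. Nt5e had an adjusted p of 0.0557 without control replicate 1, 0.105 without Bcl11b guide replicate 1 and 0.0736 without replicate 2.

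Of 9 ILC3 and type 17 genes tested in ILC2/b6, 1 rose, 1 fell and 7 were not called, 2 being called when adjusted over the list alone, with a positive median (0.06) and mean (0.04) and a test pointing down (camera adjusted p = 0.953; adjusted p = 0.963 with an estimated correlation). Ahr rose by 0.54 and Maf fell with -0.38. Of 18 trafficking and adhesion genes, 3 rose, 3 fell and 12 were not called, 10 being called when adjusted over the list alone, with a median of 0.02, a mean of -0.01 and a test pointing down (camera adjusted p = 0.461; adjusted p = 0.573 with an estimated correlation). S1pr1 fell with -0.66, Itgb1 rose by 0.57, and Cxcr4 rose by 0.33. The call of Cxcr4 ended without any 1 library, with an adjusted p of 0.0516 and 0.0864 without control replicates 1 and 2 and 0.0723 and 0.233 without Bcl11b guide replicates 1 and 2. Of 5 Notch response genes, 1 rose, 1 fell and 3 were not called, 4 being called when adjusted over the list alone, with a positive median and mean (both 0.04) and a test pointing down (camera adjusted p = 0.970; adjusted p = 0.973 with an estimated correlation). Hes1 rose by 0.29 and Notch1 fell with -0.20, with adjusted p of 0.0526 and 0.0656 without control replicate 1 and 0.183 and 0.198 without Bcl11b guide replicate 1. That of Hes1 was also 0.0641 without control replicate 2, and that of Notch1 0.0585 without Bcl11b guide replicate 2. Of 22 cytokine signal regulators, 4 rose, 8 fell and 10 were not called, 12 being called when adjusted over the list alone, with a median of 0.01, a mean of -0.03 and a test pointing down (camera adjusted p = 0.423; adjusted p = 0.564 with an estimated correlation). Stat4 rose by 0.38 (0.25 without control replicate 1), Pim1 and Il27ra fell with -0.35 and -0.33, and Il21r fell with -0.55 but had an adjusted p of 0.0786 without control replicate 1 and 0.0932 without Bcl11b guide replicate 2.

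Of 15 p53 response genes tested in ILC2/b6, 1 rose and 14 were not called, 1 being called when adjusted over the list alone (median 0.02, camera adjusted p = 0.423; adjusted p = 0.564 with an estimated correlation), and the gene that rose was Fas, a death receptor (0.40). Of 17 cholesterol synthesis genes, 2 fell and 15 were not called, 5 being called when adjusted over the list alone (median -0.04, camera adjusted p = 0.0759; adjusted p = 0.564 with an estimated correlation). These were Fdps (-0.24) and Srebf2 (-0.18), with adjusted p of 0.110 and 0.149 without Bcl11b guide replicate 1 and 0.0614 and 0.0528 without control replicate 1, and Srebf2 with 0.0978 without Bcl11b guide replicate 2. Of markers of other cell types, Fcgr3 rose by 1.01, Mcpt8, a protease of basophils, rose from 434 ± 61.2 to 792 ± 4.09 RPKM, and Cd68 fell with -0.49 but had an adjusted p of 0.0513 and 0.0518 without control replicates 1 and 2 and 0.118 without Bcl11b guide replicate 1. Hba-a1 and Hba-a2, which overlap, rose by 0.74 and 0.73, and Dcn, a stromal gene, rose from 5.65 to 11.8 RPKM. None of 4 stem and progenitor genes and not the 1 B-lineage gene was called, among them Mycn (-0.35, adjusted p = 0.103, and 0.00558 without control replicate 2), Kit (-0.07, adjusted p = 0.357) and Cd79b (0.17, adjusted p = 0.128).

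In all, 1530 of 10526 tested genes (14.5%) were called in ILC2/b6, of which 876 rose and 654 fell. At 2-fold or more there were 63, of which 51 rose and 12 fell. The libraries of the groups did not overlap for 6308 genes (59.9%), against 33.3% by chance. Of the called genes 57.3% rose as deposited, 41.7% with median-centred values and 50.8% with quantile normalization. Without Bcl11b guide replicate 1 the count was 923, without replicate 2 it was 807, and without the expression filter it was 615. Of the 71 named genes called in ILC2/b6, 16 lost the call without 1 library, against 1 of 79 in Scid.adh.2c2. Without the expression filter, which tests more genes, 25 lost it. These were Runx2 (adjusted p = 0.0587), Il18rap (0.0521), Icos (0.0541), Ctla4 (0.0660), S1pr1 (0.0530), Pkm (0.0622), Stat4 (0.128), Mir5130 (0.0770), Fos, Ets1, Mir6970, Iapp, Hes1, Notch1, Nt5e, Cxcr4, Cd68, Mcm2, Ifi27, Ddx58, Bst2, Dusp2, Fdps, Srebf2 and Il21r. Without the mean-variance trend 13 of these lost it, namely Ets1, Mir6970, Iapp, Notch1, Mcm2, Ifi27, Ddx58, Bst2, Fos, Dusp2, Fdps, Srebf2 and Stat4. The calls of Cxcr4, Ddx58 and Bst2 ended with median-centred values, those of Iapp, Hes1, Cxcr4, Mcm2 and Ddx58 with quantile normalization, and, besides those given above, those of Mir6970, Notch1 and Fdps in the joint fit. That of Scarna17 ended with voom weights, chosen after seeing the data (0.103).

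The difference between lines asks whether the effect of the guide is specific to the cell type. The data used here do not show how far Bcl11b was lost in either line. Unequal loss between the lines therefore cannot be told apart from a difference between cell types. Il2rb rose in Scid.adh.2c2 and stood in ILC2/b6 at 153 RPKM with the control guide and 149 RPKM with the Bcl11b guide (difference, ILC2/b6 minus Scid.adh.2c2, of -5.89 ± 0.08, adjusted p = 1.39e-08). Cma1 rose in ILC2/b6 and was near 0 in Scid.adh.2c2, so the difference (3.01 ± 0.14, adjusted p = 1.34e-06) repeats the change in ILC2/b6. With voom weights on recovered reads, chosen after seeing the data, the difference was 0.77 and was not called (adjusted p = 0.506). Fabp4, a fatty acid carrier, fell from 46.4 to 13.2 RPKM in Scid.adh.2c2 and rose from 0.686 to 2.33 RPKM in ILC2/b6 (3.003, adjusted p = 0.000832). The changes of all 22 interferon response genes differed, 22 of them more positive in Scid.adh.2c2. Those of all 9 Notch response genes tested in either line differed, 9 of them more positive in ILC2/b6. A gene hardly expressed in a line can show no change there, so its difference repeats the change in the other line. Of genes tested in both lines, a restriction chosen after seeing the data, all 10 interferon and all 5 Notch response genes differed, in these directions. Of 23 NK and innate effector genes 16 were more positive in Scid.adh.2c2 and 3 in ILC2/b6 (of 8 tested in both lines, 5 and 1), and of 21 trafficking and adhesion genes 16 and 2 (of 12, 11 and 1). Of 17 cholesterol synthesis genes 10 were more positive in ILC2/b6, as were 15 of 23 glycolysis and hypoxia genes (10 of 17 and 15 of 21 tested in both).

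Of 11600 genes tested in either line, 5234 (45.1%) differed, 2089 more positive in ILC2/b6 and 3145 more positive in Scid.adh.2c2. At 2-fold or more 936 differed, 227 and 709 in these directions. Among the 9147 genes tested in both lines 4154 differed, 1601 and 2553 in these directions. With median-centred values the directions held 3376 and 2328 genes, and with quantile normalization 3310 and 2362. Of the 545 genes with different transcript models in the tables, 255 differed.

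Calls in both lines ask for effects that the lines have in common. Among 9147 genes tested in both, 366 rose in both lines, where 213 would be shared if the calls were independent (odds ratio 3.03, one-sided Fisher's exact p = 2.88e-39, adjusted over 8 comparisons p = 2.30e-38). Those that fell in both numbered 131, against 106 (odds ratio 1.36, one-sided Fisher's exact p = 0.00284, adjusted p = 0.00568). Genes that rose in Scid.adh.2c2 and fell in ILC2/b6 numbered 202, against 166 (odds ratio 1.40, one-sided Fisher's exact p = 0.000272, adjusted p = 0.000725), and those with the reverse pattern 87, against 135. The counts under independence do not allow for expression level or spread, which affect the calls in both lines. The overlap was not repeated with median-centred or quantile values. At 2-fold or more, 8 genes rose in both against 0.9 (odds ratio 14.8, one-sided Fisher's exact adjusted p = 5.60e-06), among them Fcer1g, Slc2a6 and Txk, a kinase of the Tec family. Opposite changes were also more frequent than under independence, though few. At that threshold 2 genes rose in Scid.adh.2c2 and fell in ILC2/b6, against 0.3 (odds ratio 12.2, one-sided Fisher's exact adjusted p = 0.0389). The reverse pattern had 1 gene, against 0.1 (odds ratio 7.83, adjusted p = 0.171), and 0 genes fell in both. Across genes the log2 fold changes had a Pearson r of 0.102 and a Spearman rho of 0.107; genes are not independent replicates.

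**Figure D2:**
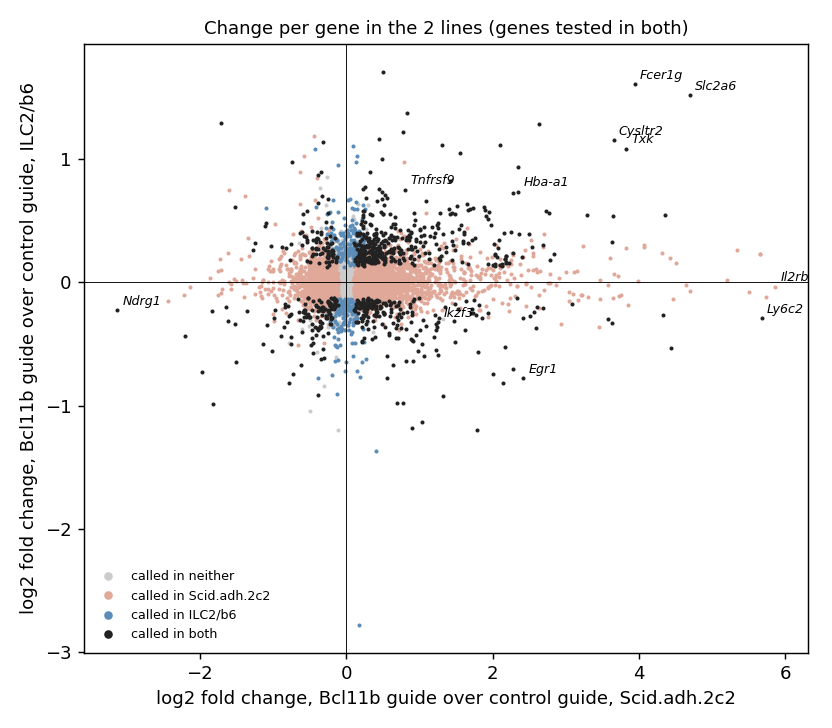
Log2 fold change with the Bcl11b guide in Scid.adh.2c2 (x axis) and in ILC2/b6 (y axis) for the 9147 genes tested in both lines, 1 point per gene, coloured by the line or lines in which the gene was called. The fold changes had a Pearson r of 0.102 across genes.

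The peak lists ask where Bcl11b binds in each line. In Scid.adh.2c2 there were 17874 Bcl11b peaks, of which 35.8% were at promoters, and in ILC2/b6 21677, of which 23.4% were. Of the Scid.adh.2c2 peaks 7709 overlapped a peak of ILC2/b6 (43.1%, 95% Wilson interval 42.4 to 43.9), which were 35.6% of the ILC2/b6 peaks (34.9 to 36.2). Shifted peaks overlapped at 0.650% and 0.536%. Peaks in both lines were at promoters more often, 53.1% of them in Scid.adh.2c2 and 49.1% in ILC2/b6, against 22.8% and 9.24% of peaks in 1 line only. Of the quartile of peaks with the highest scores 60.4% were shared in Scid.adh.2c2 and 44.6% in ILC2/b6, and of the lowest quartile 22.8% and 26.5%. For GATA3, 47.3% of 36973 Scid.adh.2c2 peaks and 51.9% of 33709 ILC2/b6 peaks were shared, for Runx1 50.7% of 13664 and 26.4% of 26258, and for Runx3 60.4% of 20523 and 27.6% of 44938.

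By the authors' score, the highest Bcl11b peak in Scid.adh.2c2 only (chr15:74917126-74917362, score 3040.2) lay between genes, 25123 bp from the start of Ly6c2, and overlapped a Runx3 peak. The next peaks in that line only were nearest Rdm1 (chr11:101503356-101503592, score 522.1) and Elfn2 (chr15:78557229-78557465, score 323.4). Of shared peaks the highest in the Scid.adh.2c2 list were in intron 4 of Hgsnat (chr8:27080127-27080363, score 2182.9), nearest Rdm1 (chr11:101506713-101506949, score 687.8) and in Rn45s, the ribosomal RNA precursor (chr17:39982036-39982272, score 591.7). In the ILC2/b6 list they were in Rn45s (chr17:39982048-39982302, score 2144.0), in intron 5 of Mocos (chr18:24831291-24831545, score 633.2) and at the promoter of Pisd-ps3 (chr11:3023964-3024218, score 437.7). In ILC2/b6 only they were in an intron near Txndc11 (chr16:11144075-11144329, score 433.1), nearest Pex2 (chr3:5860501-5860755, score 419.9) and in intron 7 of Sfi1 (chr11:3068725-3068979, score 402.8). The Txndc11 and Pex2 peaks lie in sequence annotated as ribosomal RNA repeats, where reads can map to many places. These scores stand far above the medians of 27.6 in Scid.adh.2c2 and 27.3 in ILC2/b6. The Hgsnat, Rdm1 and Sfi1 peaks overlapped no partner peak in either line. The input libraries were not used, so whether the highest scores mark Bcl11b binding was not tested.

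Co-occupancy asks which partner factors lie with Bcl11b. In Scid.adh.2c2 a Runx1 peak lay at 66.9% of shared Bcl11b peaks and 56.9% of peaks in that line only (odds ratio 1.53, Fisher's exact p = 2.40e-42, adjusted p = 7.20e-42), and a Runx3 peak at 78.3% and 69.9% (odds ratio 1.55, Fisher's exact p = 3.34e-36, adjusted p = 8.02e-36). A GATA3 peak lay at 16.7% and 21.3% (odds ratio 0.74, Fisher's exact p = 7.81e-15, adjusted p = 1.04e-14). In ILC2/b6 GATA3 lay at 20.7% of shared peaks and 42.9% of peaks in that line only (odds ratio 0.346, Fisher's exact p = 9.88e-249, adjusted p = 1.19e-247). Runx1 lay at 69.1% and 72.0% there (odds ratio 0.868, Fisher's exact p = 5.82e-06, adjusted p = 6.98e-06) and Runx3 at 87.7% and 83.5% (odds ratio 1.41, Fisher's exact p = 6.60e-17, adjusted p = 1.13e-16). Of all Bcl11b peaks 80.1% in Scid.adh.2c2 and 90.2% in ILC2/b6 overlapped at least 1 of the 3 partners, against 0.455% to 1.21% for shifted peaks of single partners. Among the higher-scoring peaks of each list the odds ratio in Scid.adh.2c2 was 0.981 for Runx1 and 1.01 for Runx3, and that of Runx1 in ILC2/b6 was 0.509, and 0.550 for equal numbers of peaks. Outside promoters, a split chosen after seeing the data, GATA3 in Scid.adh.2c2 turned, at 29.7% of shared peaks and 26.4% of peaks in that line only (odds ratio 1.21). In ILC2/b6 it lay there at 33.2% and 45.6% (odds ratio 0.690, against 0.346 for all peaks).

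**Figure D3:**
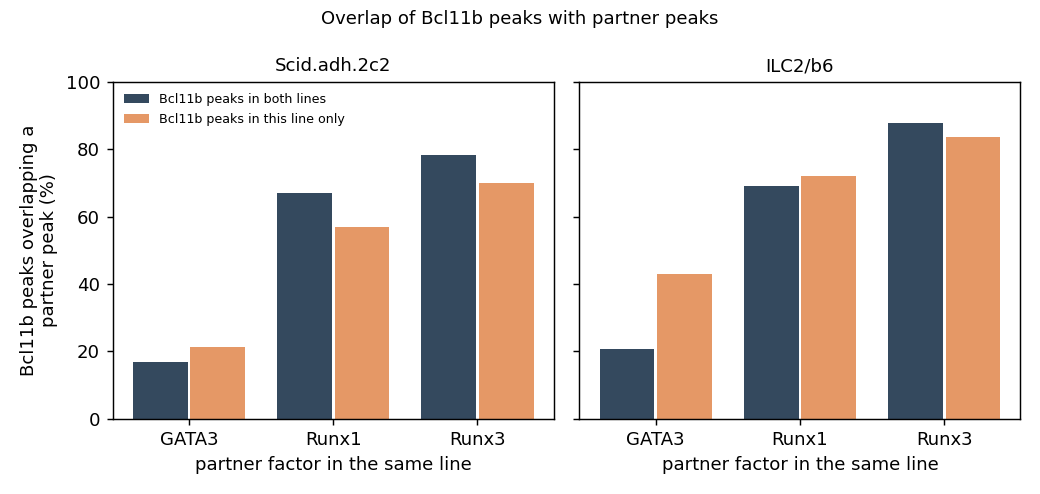
Percent of Bcl11b peaks that overlap a GATA3, Runx1 or Runx3 peak of the same line, as bars from 0, for peaks shared between lines and peaks in 1 line only, in Scid.adh.2c2 and ILC2/b6. In ILC2/b6 GATA3 lay at 20.7% of shared peaks and 42.9% of peaks in that line only, and outside promoters at 33.2% and 45.6%.

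Peaks at changed genes set binding beside the effect of the guide. Runx3 had 11 Bcl11b peaks in Scid.adh.2c2, the highest-scoring at its promoter (chr4:134676310-134676546, score 172.6) and shared with ILC2/b6. Tcf7 had a peak in Scid.adh.2c2 only, at -35555 bp from its start (chr11:52131953-52132189, score 197.7), and Rag1 had one at its promoter that overlapped GATA3, Runx1 and Runx3 peaks (chr2:101489623-101489859, score 54.5). Notch3 had one in intron 1 (chr17:32301280-32301516, score 22.3) and Il2rb one at -17068 bp from its start (chr15:78342446-78342682, score 23.5). In ILC2/b6 Il13 had a shared peak at -1635 bp from its start (chr11:53449712-53449966, score 209.0). Il5 and Areg had peaks at their promoters (chr11:53533310-53533564, score 64.8, and chr5:91568537-91568791, score 46.7). The highest-scoring peak annotated to Cma1 lay 21870 bp from its start (chr14:56541515-56541769, score 139.9). Tnfrsf9 had a shared peak in an intron (chr4:150298405-150298659, score 312.4), and Cd244 one in intron 1 (chr1:173492090-173492344, score 37.4). Bcl11b itself had peaks in both lines, the highest at chr12:109164457-109164693 (score 114.9) in Scid.adh.2c2 and chr12:109231336-109231590 (score 43.1) in ILC2/b6. Of the named changed genes 59 of 79 in Scid.adh.2c2 and 53 of 71 in ILC2/b6 had a Bcl11b peak. All 21 glycolysis and hypoxia genes tested in Scid.adh.2c2 had one, as did 22 of 23 T-lineage identity genes and 12 of 22 interferon response genes, against 73.5% of all genes tested. In ILC2/b6 29 of 30 ILC2 identity and effector genes and 4 of 10 interferon response genes had one, against 70.7% of all.

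In Scid.adh.2c2 75.7% of changed genes and 70.5% of other tested genes had a Bcl11b peak (odds ratio 1.30, Fisher's exact p = 6.18e-09, adjusted over 84 comparisons p = 1.62e-08; odds ratio 1.26 within strata of expression). In ILC2/b6 79.5% and 69.2% did (odds ratio 1.73, Fisher's exact p = 3.91e-17, adjusted p = 1.49e-16; 1.67 within strata). Of genes changed at least 2-fold, 70.7% had a peak in Scid.adh.2c2 (odds ratio 1.01, Fisher's exact p = 0.967, adjusted p = 0.967; odds ratio 1.247 within strata, Cochran-Mantel-Haenszel adjusted p = 0.0166) and 58.7% in ILC2/b6 (odds ratio 0.632, Fisher's exact p = 0.0760, adjusted p = 0.101; 0.804 within strata, adjusted p = 0.460). The following splits were chosen after seeing the data. A peak lay at 82.6% of the genes that fell at least 2-fold in Scid.adh.2c2 (odds ratio 1.98, Fisher's exact adjusted p = 7.44e-04) and 67.7% of those that rose at least 2-fold (odds ratio 0.876, Fisher's exact adjusted p = 0.174). The split by direction over all called genes depends on the scaling, and peaks at genes were compared for values as deposited only. Over all called genes of Scid.adh.2c2, as deposited, the order of rises and falls was reversed. A peak lay at 77.1% of those that rose (odds ratio 1.41, and 1.407 within strata, Cochran-Mantel-Haenszel adjusted p = 3.51e-10). It lay at 73.4% of those that fell (1.156, and 1.075 within strata, Cochran-Mantel-Haenszel adjusted p = 0.281). Without strata, peaks at promoters were as frequent at changed as at other genes, 56.2% and 56.3% in Scid.adh.2c2 (odds ratio 0.993) and 41.6% and 41.7% in ILC2/b6 (0.997). Within strata they were rarer at genes that fell in Scid.adh.2c2 (odds ratio 0.829, Cochran-Mantel-Haenszel adjusted p = 1.21e-03). At genes that rose there the odds ratio within strata was 0.988 (Cochran-Mantel-Haenszel adjusted p = 0.825). At genes changed at least 2-fold promoter peaks were rarer than at genes not called, at 37.5% in Scid.adh.2c2 (odds ratio 0.464, Fisher's exact adjusted p = 2.51e-23) and 17.5% in ILC2/b6 (odds ratio 0.296, Fisher's exact adjusted p = 1.06e-04). Peaks outside promoters lay at 41.3% of changed and 29.9% of other genes in Scid.adh.2c2 (odds ratio 1.66, Fisher's exact adjusted p = 1.04e-31) and at 62.3% and 44.0% in ILC2/b6 (odds ratio 2.10, Fisher's exact adjusted p = 7.98e-39). Of the genes that fell at least 2-fold in Scid.adh.2c2, 74.4% had one (odds ratio 6.83, Fisher's exact adjusted p = 6.38e-31) and of those that rose at least 2-fold, 54.5% (odds ratio 2.81, Fisher's exact adjusted p = 5.31e-34), while in ILC2/b6 50.8% of genes changed at least 2-fold did (odds ratio 1.32, Fisher's exact adjusted p = 0.366). Over all called genes of Scid.adh.2c2, 43.9% of those that rose (odds ratio 1.835) and 37.4% of those that fell (1.405) had a peak outside promoters. Peaks in the line alone lay at 42.9% of changed and 34.2% of other genes in Scid.adh.2c2 (odds ratio 1.44, Fisher's exact adjusted p = 3.52e-18), and at 59.5% and 37.9% in ILC2/b6 (odds ratio 2.41, Fisher's exact adjusted p = 4.38e-54). They lay in Scid.adh.2c2 at 76.2% of the genes that fell at least 2-fold (odds ratio 6.14, adjusted p = 3.28e-27) and 47.8% of those that rose (1.76, adjusted p = 3.86e-11). In ILC2/b6 the shares were 50.0% (odds ratio 1.64, adjusted p = 0.436) and 51.0% (1.71, adjusted p = 0.0817), and 50.8% for both directions together (1.69, adjusted p = 0.0528; 1.79 within strata, Cochran-Mantel-Haenszel adjusted p = 0.0327). Genes that fell at least 2-fold in Scid.adh.2c2 were mostly low in ILC2/b6. The 152 with the same transcript model had median control levels of 11.05 RPKM in Scid.adh.2c2 and 0.42 RPKM in ILC2/b6. Whether a peak is shared may therefore go with expression in 1 line, and the strata, made within a line, do not remove this. Shared peaks lay at 52.6% of changed and 49.9% of other genes in Scid.adh.2c2 (odds ratio 1.11, Fisher's exact adjusted p = 0.0117, and 1.07 within strata, adjusted p = 0.146) and at 45.0% and 49.8% in ILC2/b6 (0.822, adjusted p = 7.56e-04). They lay in Scid.adh.2c2 at 30.2% of the genes that fell at least 2-fold (0.436, Fisher's exact adjusted p = 7.70e-07) and 44.8% of those that rose at least 2-fold (0.815, adjusted p = 0.0203, and 0.973 within strata, adjusted p = 0.781), and in ILC2/b6 at 20.6% of genes changed at least 2-fold (0.262, adjusted p = 6.25e-06). Over all genes that rose in Scid.adh.2c2, shared peaks lay at 56.5% (odds ratio 1.304, Fisher's exact adjusted p = 1.41e-08). Over all that fell there they lay at 46.5% (0.875, Fisher's exact adjusted p = 0.0153).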

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

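Of the tests below, those for carried-over reads and for mast cell markers under 1 RPKM were chosen after the result was seen. The change with the Bcl11b guide differed between the lines for 5234 genes by the limma interaction contrast. The largest differences, ILC2/b6 minus Scid.adh.2c2, were log2 3.01 for Cma1, 3.003 for Fabp4, 2.94 for Tpsb2, 2.93 for Mir6954 and 2.91 for Ndrg1, with SE 0.14, 0.44, 0.09, 0.57 and 0.48. In the other direction they were -6.23 for Ly6g, -5.97 for Ly6c2, -5.89 for Il2rb, -5.85 for Ccl3 and -5.58 for Ly6c1, with SE 0.15, 0.12, 0.08, 0.18 and 0.10, and Ly6c1 has a different transcript model in each table. Of these 10 genes, 6 were tested in both lines. Tpsb2 is listed at 0 in every Scid.adh.2c2 group, Cma1 in the Scid.adh.2c2 control libraries and Mir6954 in the ILC2/b6 control libraries, and Ly6g had means under 1 RPKM in ILC2/b6. The differences of Tpsb2 and Cma1 repeat their folds in ILC2/b6 (2.94 and 3.20), and that of Mir6954 depends on the pseudocount.

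Chymase and tryptase genes were higher with the Bcl11b guide in ILC2/b6, and a larger share of admixed mast cells would raise every abundant mast cell transcript. The other 10 markers tested had a median log2 fold change of 0.17 ± 0.204 (SE), below the 1 set beforehand. That decides nothing, since the line itself has high levels of some, such as Cyp11a1 (891 RPKM with the control guide), Srgn (1070 RPKM) and Tph1 (715 RPKM), which would hide a small share. The 16 markers under 1 RPKM in the control libraries had a median log2 ratio of 0.004 ± 0.095 (SE). Among them Cpa3 did not exceed 0.056 RPKM in any library and Fcer1a 0.028 RPKM, and Ms4a2 was listed at 0, against 24.2 RPKM of Cma1 and 44.8 RPKM of Tpsb2 with the Bcl11b guide. Gata2, a factor of mast cells, went from 0.149 and 0.158 to 0.591 and 0.653 RPKM and Mitf from 0.263 and 0.38 to 0.542 and 0.556 RPKM, and neither was tested. The levels of Cpa3, Fcer1a and Ms4a2 argue against admixture as the source of the chymase and tryptase reads. Mcpt1, Mcpt2, Mcpt4 and Mcpt8 rose. A direct or indirect effect of the Bcl11b guide on protease genes may remain, and reads shared between paralogs of this family were not tested.

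Interferon response genes were higher with the Bcl11b guide in Scid.adh.2c2, and a response to guide delivery is a technical explanation. The control libraries carry a guide too, so such a response cancels within each line if both guides were delivered alike. The median of the list in ILC2/b6, 0.136 ± 0.062 (SE, 10 genes), below the 0.5 set beforehand, was therefore bound to be low and excludes nothing. Unequal delivery of the guides in Scid.adh.2c2 cannot be told apart from an effect of the Bcl11b guide on its target, since each guide is a group. Ifng made by the cells is a candidate source: its mean was 5.08 RPKM in the Bcl11b guide libraries, against 0.437 and 0.335 RPKM in the control libraries, where 3 reads are worth 0.0570 to 0.0718 RPKM. Whether the protein was made or sensed was not measured.

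Genes that rose in Scid.adh.2c2 may be genes of the ILC2/b6 line. Of 429 genes that rose at least 2-fold, 57.34% had a higher RPKM in the ILC2/b6 than in the Scid.adh.2c2 control libraries, against 23.8% (19.8 to 28.0 in 95% of 1000 draws) of uncalled genes matched on control level. This compares levels across tables, and it was narrowed to genes with at least 1 RPKM in the control libraries and the same transcript model, which the written prediction did not say; at any level it was 56.4% of 644. Reads carried over from ILC2/b6 would raise its most abundant transcripts together, and the 20 that were low in the Scid.adh.2c2 control libraries had a median log2 ratio of 0.158 ± 0.198 (SE). Il5 went from 0.776 to 0.751 RPKM while Il13 went from 1.51 to 8.04 RPKM, which argues against carry-over.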

How the results depend on the processing

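The voom weights, the splits by promoter and the restriction to genes tested in both lines were chosen after seeing the data. Counts and shares gave 136 values over 18 results, of which 104 stayed within their bounds, 23 moved, 5 reversed, 2 passed the threshold anew and 2 no longer did. For counts of genes the bounds apply to the total and not to the split by direction. With median-centred and quantile values the direction with more genes turned, in Scid.adh.2c2 and for the difference between lines. Those turns are not among the 5 that reversed. Of 2516 values for named genes, 2374 were the same, 95 lost and 47 gained a call, and 0 reversed; of 270 for lists, 238 were the same, 30 lost and 2 gained a call; of 170 for named differences, 169 were the same, and Cma1 lost its call with voom weights. Leaving out 1 library, with a lone library assumed to vary like the other group, gave 3760 to 6878 genes in Scid.adh.2c2, 807 to 2099 in ILC2/b6 and 4049 to 5301 that differed between lines, 9 to 9 lists in Scid.adh.2c2 and 3 to 6 in ILC2/b6, and Bcl11b log2 fold changes of -0.08 to -0.001 and 0.06 to 0.16. A minimum of 2-fold gave 862, 63 and 936 genes and 8 in both lines, by construction fewer. Without a filter ILC2/b6 had 615 genes and 3 lists. Bcl11b mRNA in Scid.adh.2c2 passed at -0.17 (median-centred) and -0.11 (quantile). With an estimated correlation, which has little power at 2 libraries per group, 0 lists were called in Scid.adh.2c2 and 0 in ILC2/b6. The shared percent of Bcl11b peaks in Scid.adh.2c2 was 39.8 with an overlap of 0.5 of the shorter peak, 42.2 for centres within 200 bp, 39.47 for the higher-scoring peaks, 37.7 for equal numbers and 31.0 outside promoters; in ILC2/b6 32.8, 34.8, 32.5, 37.7 and 21.4. Odds ratios turned or lost their call at 0.981 (Runx1) and 1.01 (Runx3) for higher-scoring peaks in Scid.adh.2c2, 1.21 (GATA3, outside promoters), 1.01 and 0.632 for genes changed 2-fold, and 0.993 and 0.997 for promoter peaks. The cause was not tested. With replicate number as a block, 5921 and 2258 genes were called, 4878 differed, 698 were called in both lines and 9 and 4 lists passed, with partner factors at 0.0524 and cell cycle at 0.0527 in ILC2/b6. Residuals correlated between equal numbers at 0.037 and 0.106, and the labels do not say whether the numbers pair the samples. The limit of 1 RPKM for tested genes was the chosen filter and was not set by depth.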

Other observations

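The selections below were made after the results were seen. Genes of the lists moved in opposite directions in the lines. The type 2 cytokine genes Il4 and Il13 rose in Scid.adh.2c2 by 2.59 and 2.18 log2 units and fell in ILC2/b6 with -0.37 and -0.52 (differences -2.96 and -2.70). Il13 was low in Scid.adh.2c2, at 2.21 and 0.816 RPKM in the control libraries and 7.65 and 8.43 RPKM with the Bcl11b guide. Its fall in ILC2/b6 was not called in the limma joint fit of the 8 libraries (adjusted p = 0.223). Egr1, an immediate early factor, rose by 2.42 and fell with -0.78 (difference -3.20). Ikzf3, Prdm1 and Itgal rose by 1.26, 1.71 and 1.73 and fell with -0.32, -0.25 and -0.25. Deptor fell with -1.52 in Scid.adh.2c2 and rose by 0.61 in ILC2/b6 (difference 2.13), as did Pdk1 (-1.27 and 0.26).

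The 8 genes that rose at least 2-fold in both lines were Slc2a6 (4.70 in Scid.adh.2c2 and 1.52 in ILC2/b6), Fcer1g (3.94 and 1.61), Txk (3.83 and 1.08), Cysltr2, a leukotriene receptor (3.65 and 1.151), Avil (2.64 and 1.29), Tlr1 (2.11 and 1.12), Gpr162 (1.55 and 1.05) and Naglu (1.32 and 1.12). Bcl11b peaks in Scid.adh.2c2 only overlapped a partner peak of that line at 77.0% and a partner peak of ILC2/b6 at 39.0%, where Runx3 gave 34.1%, Runx1 15.9% and GATA3 7.61%. Bcl11b peaks in ILC2/b6 only overlapped a partner of that line at 89.6% and a partner of Scid.adh.2c2 at 14.4%, where GATA3 gave 9.03%, Runx3 6.29% and Runx1 2.66%.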
